A study of Saccharomyces cerevisiae with 5 samples.

How the data were processed

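Per the labels' protocols, cells precultured on solid YPGA were grown in HC-LN-based medium with 1% (w/v) DEH, glucose or mannitol, total RNA was taken by acid phenol-chloroform, and CAGE libraries were made by cap trapping with a DNAFORM kit and sequenced on a NextSeq500. The submitters' processing notes list BWA, HISAT2 and the genome build mm9, with no version or role; mm9 is a mouse build, while the deposited cluster names carry the sequence names of yeast S288C R64, so R64 was used here. The sources used here state no clustering tool, no filter and no rule for assigning clusters to genes.

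The values are normalised signal, tags per consensus cluster scaled by the authors to CPM of each library, as named in the deposited file. The design assumed CPM. The unit was recorded as signal because a cluster assigned to several genes is repeated in the deposited table, so that a plain column sum passes the total that CPM allows. The table held 29960 lines and 27176 distinct clusters, and each cluster was used 1 time. No PCR duplicate removal by molecular identifiers is stated, so intervals cover counting error only.

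The CPM of 1 read was found as the step between low values of each library (0.0503 to 0.106 CPM), and all values were whole multiples of it within 0.15 of a read. The lowest listed value was 5 to 10 reads, and lower ones were listed at 0. Read counts for intervals and tests were the CPM divided by this step. Cluster starts were shifted by 1 base to 1-based coordinates after a check on 204 clusters of 1 base, of which 65.7% began on a purine after a pyrimidine with the shift and 7.84% without it.

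The files, groups, comparisons, filters, limits, gene lists and most alternatives were set before the data were examined. The 5 libraries form 5 groups by strain and medium with 1 library in each, from the sample labels. The comparisons were DEH against glucose in each strain and in both, mannitol against glucose and DEH against mannitol in BY_DEH++, the strains in DEH and in glucose, the overlap of DEH and mannitol calls, and start site use within genes.

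A gene's value was the sum of clusters on its strand that overlap the window from 500 bp upstream to 100 bp downstream of the start of its coding sequence, each cluster going to the nearest start. Of 6021 protein-coding genes 5547 had a cluster and 5276 reached 10 CPM in at least 1 library. Of 5398 clusters with 10 CPM or more in windows, 89.5% were given to the same gene in the deposited table. Folds were log2 ratios of CPM + 1, and a gene was called at 4-fold. For both strains, a gene had to pass in each with the same sign. The overlap expected from independent lists was the product of the list sizes divided by the number of genes. Ratios carry 95% intervals from the 2 read counts. Genes were marked uncertain where the 50 bases from the midpoint of the main cluster recur in the genome (31 genes, 0.588%). These are called the first 50 bases of a gene below.

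Genes named by rule were the 12 with the largest fold in both strains in each direction for DEH against glucose (ranked by the smaller fold of the strains), 10 for mannitol against glucose, 6 for DEH against mannitol, 8 for the strains in DEH and 5 for the strains in glucose. All measured members of the mannitol and sorbitol, mating type and marker lists were named, and members with large folds in the other lists. The lists, written from general knowledge of yeast, were counted at 2-fold, and each median was placed among 10000 random lists matched in 20 bins of mean level when at least 5 genes were measured. The lists cover hexose transporters, other glucose-repressed sugar genes, mannitol and sorbitol use, glycolysis, gluconeogenesis and the glyoxylate cycle, the tricarboxylic acid cycle, oxidative phosphorylation, fatty acid oxidation, the pentose phosphate pathway, glycerol, trehalose and glycogen, general and oxidative stress, ribosomal proteins, ribosome biogenesis, genes under Gcn4, iron, phosphate, nitrogen catabolite repression, thiamine, Cyc8-Tup1 repression, the cell wall, histones and S phase, both mating types, meiosis, selection markers and mitochondrially encoded genes. Start site use was the share of a gene's CPM in its main cluster, in genes with at least 2 clusters of 10 CPM or more in some library and with 10 CPM or more in both libraries compared.

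Alternatives set before the data were examined were a 2-fold limit, pseudocounts, filters, median-of-ratios scaling (factors of 0.786 to 1.15 over 4528 genes), upper-quartile scaling, clusters as assigned in the deposited table, a binomial test of read counts between libraries, a limma fit of log2(CPM + 1) with medium and strain as additive terms, and a 30-point limit for start sites. The binomial test compares libraries, not conditions, and left every count of calls unchanged. Added after the data were seen were a filter without the mannitol library, removal of ribosomal protein genes and removal of genes with recurring first bases. Subtraction of the median of genes of like span was added then too. Span was the length of the annotated gene, introns included.

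The calling rule was tested on simulated data that held counting noise only, so the test says nothing of variation between cultures. Every library was drawn from the BY_DEH++ glucose values. Changes were planted only in genes with at least 50 CPM in both glucose libraries, so recovery was not tested in genes of lower level. In DEH against glucose in both strains the rule returned 50 of 50 genes planted at 8-fold, 4 of 50 at 4-fold and 0 of 50 at 2-fold, and called 0 unchanged genes. The limma fit returned 50 of 50 at each size. The planted changes were the same in both strains, so its residual held counting noise only and this recovery says little of real cultures. The software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1. Raw reads were not used here, and the introduced genes of the DEH pathway were not analysed here. 1 further gene list, chosen after the data were seen, is not reported here.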

Results

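The data are cap analysis of gene expression (CAGE) libraries, which sequence the capped 5' ends of RNAs and so count transcripts at their start sites, from Saccharomyces cerevisiae. The strains, BY_DEH+ and BY_DEH++, are described in the sources used here by name alone. DEH is 4-deoxy-L-erythro-5-hexoseulose uronate, the sugar acid left when alginate is cut down to its monomers, and mannitol is a sugar alcohol; both come from brown seaweed. Cultures of 10 mL grew at 30 °C on 1% (w/v) of the named carbon source. BY_DEH+ was sampled in DEH and in glucose, and BY_DEH++ in DEH, glucose and mannitol, with 1 library in each of these 5 groups.

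The BY_DEH+ culture in DEH went from an optical density (OD600) of 0.2 to 0.63 in 3 days, and the BY_DEH++ culture in DEH from 0.05 to 0.55 in 2 days. The mannitol culture went from 0.02 to 0.79 in 1 day. The glucose cultures grew overnight, from 0.05 to 0.91 in BY_DEH+ and from 0.05 to 0.95 in BY_DEH++. Culture time and final density thus differed between the media, so medium and culture stage cannot be told apart in any comparison of media. Library depth, recovered from the steps between low values, was 10.7 M reads for BY_DEH+ in DEH, 9.43 M for BY_DEH+ in glucose, 19.9 M for BY_DEH++ in DEH, 13.3 M for BY_DEH++ in glucose and 10.5 M for BY_DEH++ in mannitol. Values are in CPM, read counts scaled to library size. A value of 10 CPM rested on 94 to 199 reads, with a 95% Poisson interval of 8.06 to 12.2 CPM in the shallowest library and 8.66 to 11.5 CPM in the deepest. These intervals cover counting error only. Values below about 0.5 CPM were listed at 0 in the deposited table.

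No group had a replicate, so no difference between 2 groups below has a replicate check or a p-value. A gene is called higher or lower by the size of its fold alone, at 4-fold or more on the log2(CPM + 1) scale among 5276 genes. List members are counted at 2-fold. The median log2 fold of all genes was 0.12 for DEH over glucose in BY_DEH+, -0.11 in BY_DEH++, -0.50 for mannitol over glucose, 0.36 for DEH over mannitol, -0.23 between the strains in DEH and -0.03 between them in glucose. Median-of-ratios scaling moved these medians by -0.11, 0.07, 0.40, -0.33, 0.20 and 0.02, in that order, so the median of a gene list is to be read against the median of all genes.

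The first question was how yeast transcription in DEH differs from that in glucose. In both strains the DEH libraries held more RNA from genes for growth on non-fermentable carbon, and less from genes for iron uptake. ADH2, the alcohol dehydrogenase that oxidises ethanol (chromosome XIII, 873291 to 874337), stood at 11769 CPM in DEH and 30.7 CPM in glucose in BY_DEH+, a ratio of 384 (95% counting interval 342 to 432). In BY_DEH++ it stood at 7929 and 22.8 CPM, a ratio of 349 (311 to 391). At the other end, FIT1, a cell wall mannoprotein of siderophore iron uptake (chromosome IV, 1503314 to 1504900), stood at 0.84 CPM in DEH and 270.3 CPM in glucose in BY_DEH+, and at 0.91 and 415 CPM in BY_DEH++. HXT3, a low-affinity glucose transporter (chromosome IV, 1162957 to 1164660), stood at 131 and 185 CPM in the glucose libraries and was listed at 0 in DEH in both strains.

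In BY_DEH+, 164 genes were 4-fold or more higher and 227 lower in DEH; in BY_DEH++, 184 were higher and 135 lower. The balance depended on the setting: a 2-fold limit gave 609 higher and 558 lower in BY_DEH+ and 481 and 625 in BY_DEH++. A pseudocount of 10 CPM gave 116 and 138 in BY_DEH+ and 156 and 69 in BY_DEH++, and leaving out ribosomal protein genes 84 and 135 in BY_DEH++. The calls met in 85 genes higher and 82 genes lower in both strains, where independent lists of these sizes would share 5.72 and 5.81. The pairs of libraries behind these folds share no library. Of 542 genes past 4-fold in either strain, 505 (93.2%) had the same sign in both. With a pseudocount of 10 CPM the shared calls came to 54 higher and 42 lower, and with all clusters that the deposited table assigns to a gene, 54 were higher.

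**Figure D1:**
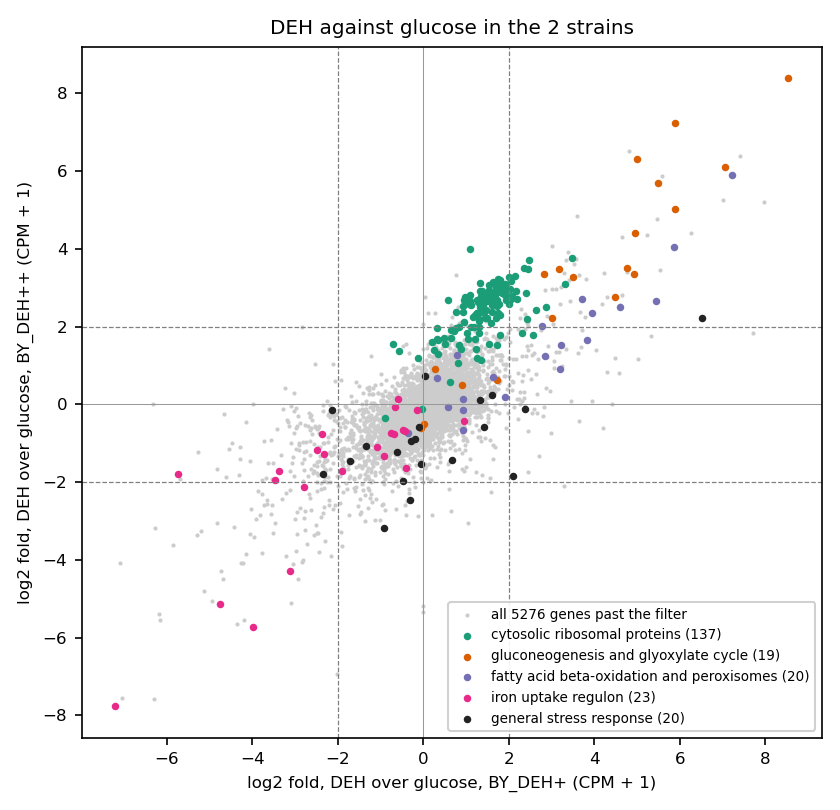
Log2 fold of DEH over glucose (CPM + 1) for each of the 5276 genes in BY_DEH+ (horizontal axis) and BY_DEH++ (vertical axis), with 5 gene lists in colour and dashed lines at 4-fold. Gluconeogenic genes lie at the upper right (list medians 4.48 and 3.36) and iron uptake genes at the lower left (-1.90 and -1.28), while the general stress genes lie lower in BY_DEH++ (-1.01) than in BY_DEH+ (-0.15).

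Of the lists with at least 5 measured genes, the gluconeogenesis and glyoxylate list had the highest median in both strains: 15 of its 19 members were at least 2-fold higher in DEH in BY_DEH+ and 14 in BY_DEH++. None was lower, and its medians of 4.48 and 3.36 lay at percentile 100 of random lists matched on expression in each strain. FBP1, the phosphatase specific to gluconeogenesis (chromosome XII, 873746 to 874792), stood at 887 CPM in DEH against 5.73 in BY_DEH+ and at 497 against 6.26 in BY_DEH++. PCK1, which makes phosphoenolpyruvate from oxaloacetate, stood at 2131 against 46.6 CPM and at 1978 against 37.0 CPM. MLS1, the malate synthase of the glyoxylate cycle, SFC1, a mitochondrial succinate-fumarate carrier, and ADY2, an acetate transporter, were among the 12 highest genes too, at 248, 525 and 1480.2 CPM in DEH in BY_DEH+ and 304, 501 and 863 CPM in BY_DEH++. ICL2, a mitochondrial 2-methylisocitrate lyase, stood at 313 and 230 CPM (229.5 before rounding) in DEH against 0.85 and 1.73 CPM in glucose, and FDH1, a formate dehydrogenase, at 51.3 CPM against 0.85 in BY_DEH+ and at 90.5 CPM in BY_DEH++, where it was listed at 0 in glucose.

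Fatty acid oxidation and peroxisome genes were higher as well, 13 of 20 in BY_DEH+ (median 2.80) and 11 of 20 in BY_DEH++ (median 1.26), each at percentile 100. CTA1, the peroxisomal catalase, stood at 872 CPM in DEH against 4.88 in BY_DEH+ and at 99.96 against 0.68 CPM in BY_DEH++. FOX2, the multifunctional beta-oxidation enzyme, stood at 592 against 9.23 CPM and at 147 against 7.99 CPM. FAT3, a protein of fatty acid uptake, stood at 382 and 58.2 CPM in DEH against 0.53 and 0.60 CPM, and PEX9, an import receptor of peroxisomes, at 128 and 37.1 CPM in DEH with glucose listed at 0. The deposited table assigns the PEX9 cluster to SPO20. DPA10 completed the 12 highest genes at 1289 and 867 CPM against 25.8 and 13.7 CPM, from a cluster that the deposited table assigns to the neighbouring gene CDA1.

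Respiratory genes were higher in part. The tricarboxylic acid cycle list had medians of 0.82 and 1.05, with 7 and 9 of 16 members higher and 2 and 0 lower. The oxidative phosphorylation list had medians of 0.56 and 1.16, with 5 and 21 of 34 higher and 1 lower in each strain. SDH2, a subunit of succinate dehydrogenase, stood at 655 and 425 CPM in DEH against 125 and 111 CPM in glucose, whereas IDH2, of mitochondrial isocitrate dehydrogenase, stood at 116 against 491 CPM in BY_DEH+ and at 841 against 550.4 CPM in BY_DEH++. Glycolytic genes were lower, 9 of 16 in BY_DEH+ (median -1.14) and 5 of 16 in BY_DEH++ (-0.70), with ENO2 at 754 and 1887 CPM in DEH against 5250.0 and 6110 CPM (6109.5). The trehalose and glycogen list was lower in both strains (medians -1.18 and -1.11, 9 of 16 members in each), as in GSY1, a glycogen synthase, at 24.7 and 28.1 CPM against 88.0 and 130.2 CPM.

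Genes for making protein were higher in DEH. Of 137 cytosolic ribosomal protein genes, 108 were at least 2-fold higher in BY_DEH+ (median 1.43) and 134 in BY_DEH++ (2.57), and none was lower. Their share of all gene CPM was 9.01% in DEH against 3.83% in glucose in BY_DEH+ and 14.997% against 3.06% in BY_DEH++. RPL20B stood at 526 and 707 CPM in DEH against 46.6 and 51.4 CPM. The ribosome biogenesis list had medians of 0.50 and 0.96, with 5 of 45 members at least 2-fold higher in BY_DEH+ and 22 in BY_DEH++. Amino acid genes under Gcn4, the regulator of the amino acid starvation response, were lower, 24 of 39 in BY_DEH+ (median -1.26) and 18 in BY_DEH++ (-0.97), with HIS4 at 70.2 and 96.8 CPM against 554 and 665 CPM.

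Iron uptake genes were lower in DEH: 13 of 23 in BY_DEH+ (median -1.90, or -1.07 with clusters as the deposited table assigns them) and 14 of 23 in BY_DEH++ (-1.28). None was higher, and both medians lay at percentile 0. FRE2, a ferric reductase, stood at 1.68 and 1.56 CPM in DEH against 72.0 and 88.4 CPM, and FIT3, a further cell wall mannoprotein, at 2499 and 10097 CPM against 26026 and 32837 CPM. LSO1, a small protein produced under iron limitation, was listed at 0 in DEH against 24.8 and 21.4 CPM. Phosphate starvation genes were lower in BY_DEH+ (12 of 17, median -1.49) and less far in BY_DEH++ (5 of 17, median -0.59), with PHO5, the secreted acid phosphatase, at 18.9 against 331 CPM and at 239 against 656 CPM.

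Hexose transporter and sensor genes were mixed in BY_DEH+, with 3 of 10 higher, 3 lower and a median of -0.03, and lower in BY_DEH++, with 6 of 10 lower, 1 higher and a median of -1.82 (-0.87 with a pseudocount of 10 CPM). HXT4, a glucose transporter, stood at 1.40 and 0.50 CPM in DEH against 187 and 283 CPM, while HXT5, the transporter of slow-growing cells, stood at 560 (559.9) and 127 CPM against 54.6 and 46.9 CPM. Of 13 genes held down by the Cyc8-Tup1 corepressor, 7 were lower and 4 higher in DEH in BY_DEH+ (median -1.36) and 10 lower and 2 higher in BY_DEH++ (median -1.86). With a pseudocount of 10 CPM these medians were -0.47 and -0.74, and with clusters as the deposited table assigns them that in BY_DEH+ was -0.55. In this list, TIR1, a cell wall mannoprotein of cold and low oxygen, was listed at 0 in DEH against 70.9 and 45.4 CPM, and IMD2, an inosine monophosphate dehydrogenase, stood at 3.74 and 14.9 CPM against 647 and 266 CPM. Of the other glucose-repressed sugar genes, 2 of 9 were higher in BY_DEH+ and 1 in BY_DEH++, with SUC2, the invertase, at 296 and 200 CPM (199.6) against 129 and 173 CPM. Their median of 0.08 in BY_DEH+ turned to -0.03 with median-of-ratios scaling, and that in BY_DEH++ was -0.34.

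Among oxidoreductase and oxidative stress genes, 7 of 23 were higher in BY_DEH+ (median 0.47) and 4 in BY_DEH++ (median -0.10). The members with the largest folds in BY_DEH+ were OYE3, GRE2 and AAD4: OYE3, an old yellow enzyme, stood at 257 and 87.2 CPM in DEH against 9.33 and 3.47 CPM, GRE2, a methylglyoxal reductase, at 837 and 393 CPM against 90.7 and 64.9 CPM, and AAD4, a putative aryl-alcohol dehydrogenase, at 88.0 and 40.0 CPM against 15.4 and 9.19 CPM. Glycerol genes had medians of 0.14 and 0.04 with 4 of 10 higher in each strain, led by STL1, the glycerol symporter, at 11.0 and 27.9 CPM in DEH and listed at 0 in glucose. Of the pentose phosphate genes, 4 of 11 were higher and 3 lower in BY_DEH+ (median -0.49), and 1 was higher and 2 lower in BY_DEH++ (-0.16). Genes under nitrogen catabolite repression had medians of -0.73 and 0.34 (2 and 5 of 16 higher, 6 and 2 lower), with PUT4, the proline permease, at 78.7 and 75.5 CPM against 6.58 and 4.07 CPM. The cell wall list had a median of 0.05 in BY_DEH+, which turned to -0.06 with median-of-ratios scaling, and -0.16 in BY_DEH++; CWP1, a cell wall mannoprotein, was higher at 169 and 129 CPM against 14.96 and 13.1 CPM. The thiamine list lay near 0 (medians -0.09 and -0.04, the latter 0.03 with median-of-ratios scaling).

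Mating genes were among those named at the lower end. SAG1, the alpha-agglutinin, stood at 72.4 and 169 CPM in glucose, was listed at 0 in DEH in BY_DEH+ and stood at 3.07 CPM in BY_DEH++. MFA2 and AGA2, genes of a cells for the a-factor pheromone and an agglutinin subunit, stood at 49.8 and 46.4 CPM in glucose in BY_DEH+ against 0.65 and 1.31 CPM in DEH. SST2, FUS1 and PRM1, genes of the pheromone response, stood at 120.2, 25.8 and 39.7 CPM in glucose in BY_DEH+ and at 2.43, 0 and 1.21 CPM in DEH, with 111, 34.4 and 71.3 CPM against 3.02, 0.80 and 0.55 CPM in BY_DEH++. Genes specific to a cells and to alpha cells were read in the same libraries: in glucose in BY_DEH+, STE2, the alpha-factor receptor of a cells, stood at 82.4 CPM and STE3, the a-factor receptor of alpha cells, at 130 CPM (129.8), and in BY_DEH++ at 106 and 231 CPM. The 4 measured genes of a cells had medians of -3.46 and -4.21 in DEH over glucose, and the 5 genes of alpha cells -2.48 and -1.18, of which 4 and 3 were 2-fold lower. MFA1, MFA2 and AGA2 reached 10 CPM in the glucose libraries alone, so their direction was set by the filter. With a pseudocount of 10 CPM the medians of the a cell genes were -2.16 and -2.57, and with clusters as the deposited table assigns them -1.55 and -2.38. MFA1 stood at 6.63 and 3.02 CPM in DEH against 20.4 and 20.8 CPM, MF(ALPHA)1 at 241 and 1025 CPM against 1352 and 1589 CPM, MF(ALPHA)2 at 0 and 2.26 CPM against 57.1 and 38.8 CPM, and AFB1 at 156 and 225 CPM against 284 and 254 CPM.

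The next question was how BY_DEH++ transcription in mannitol differs from that in glucose. The mannitol library held more RNA from ribosomal protein genes and short noncoding RNAs, and less from genes for iron uptake and glucose transport and from the zinc transporter ZRT1. Ribosomal protein genes took 25.6% of all gene CPM in mannitol against 3.06% in glucose, and 132 of 137 were at least 2-fold higher (median 3.35). RPL29 (chromosome VI, 223258 to 223437) stood at 1963 CPM against 23.1 CPM, a ratio of 84.9 (95% counting interval 75.8 to 95.3). ZRT1, the high-affinity zinc transporter (chromosome VII, 20978 to 22108), stood at 136 CPM in mannitol against 10393 CPM in glucose, and ZPS1, a zinc-responsive cell surface protein, at 5.16 against 2326 CPM. In BY_DEH+ in glucose ZRT1 and ZPS1 stood lower than in BY_DEH++ in glucose, at 4952 and 244 CPM.

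In mannitol 211 genes were 4-fold or more higher and 387 lower, so that 35.3% of calls were higher; median-of-ratios scaling gave 296 higher and 232 lower (56.1% higher) and upper-quartile scaling 278 and 250. A pseudocount of 10 CPM gave 168 higher and 182 lower, a 2-fold limit 520 and 1537, and leaving out ribosomal protein genes 97 and 387. The mannitol sample's title lacks the short sequence ending that the other 4 titles carry, and with 1 library any difference in preparation cannot be told apart from the medium.

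All 10 of the highest genes encode ribosomal proteins: beside RPL29 these were RPL37A, RPL39, RPS22B, RPL9A, RPS27B, RPL43A, RPS28A, RPL37B and RPS31, at 641 to 3842 CPM in mannitol and 11.0 to 98.6 CPM in glucose. Ribosome biogenesis genes were higher by less (12 of 45, median 0.39, percentile 100). Some respiratory genes were higher, with medians of 0.59 for the tricarboxylic acid cycle (7 of 16 higher, 2 lower) and 0.94 for oxidative phosphorylation (15 of 34 higher, 2 lower), the latter led by ATP18, a subunit of ATP synthase, at 1505 against 76.8 CPM and CYC1, cytochrome c, at 183 against 14.3 CPM. The gluconeogenesis list had a median of 0.28, with 5 of 19 members higher and 4 lower. ADH2 stood at 504 against 22.8 CPM and PCK1 at 257 against 37.0 CPM, below their levels in DEH, while YAT1 and YAT2, carnitine acetyltransferases, stood at 12.1 and 26.7 CPM against 104 and 265 CPM. Histone and S phase genes were higher (9 of 18, median 0.95), with CLB6, an S phase cyclin, at 17.1 against 0.83 CPM and HTB1 at 1905 against 648 CPM.

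Of the 23 iron uptake genes, 21 were lower in mannitol and 1 was higher (median -3.88, percentile 0). FIT1 was listed at 0 against 415 CPM, FIT3 stood at 373 against 32837 CPM, and ARN2, a siderophore transporter, at 29.9 against 1842 CPM; ATX1, a copper chaperone, was the higher member at 202 against 50.8 CPM. Of the hexose transporters and sensors 9 of 10 were lower (median -3.01), with HXT3 and HXT4 listed at 0. Genes under nitrogen catabolite repression were lower in 9 of 16 (median -1.54, or -0.88 with a pseudocount of 10 CPM and -0.84 with clusters as the deposited table assigns them) and genes under Gcn4 in 18 of 39 (-0.95). The list medians were -1.27 for thiamine (8 of 12 lower, 0 higher), -1.28 for Cyc8-Tup1 repressed genes (8 of 13 lower, 2 higher, and a median of -0.36 with a pseudocount of 10 CPM), -0.46 for glycolysis, -0.87 for other glucose-repressed sugar genes, -0.90 for the pentose phosphate pathway, -0.66 for glycerol, -0.40 for trehalose and glycogen, -0.61 for general stress, -0.48 for oxidoreductases and -0.47 each for fatty acid oxidation and the cell wall, all within the middle 95% of random lists. Within them SNZ3, of thiamine synthesis, stood at 1.15 against 50.4 CPM, HSP26, a small heat shock protein, at 9.17 against 716 CPM, TDH1, of glyceraldehyde-3-phosphate dehydrogenase, at 1303 against 17008 CPM, and CWP2, a major cell wall mannoprotein, at 9557 against 1826 CPM. The phosphate list had a median of -0.22 that turned to 0.20 with median-of-ratios scaling; PHO12 was listed at 0 against 380 CPM (379.7) and SPL2, an inhibitor of low-affinity phosphate transport, stood at 1082 against 208 CPM. The lowest genes also held VEL1 and YPL257W-B, listed at 0 against 305 and 267 CPM, and CUP1-1, a copper metallothionein, at 25.3 against 2488 CPM. VEL1 and YPL257W-B stood at 3.08 and 1.49 CPM in BY_DEH+ in glucose, and at 1.51 and 61.4 CPM in BY_DEH++ in DEH. Their high values in the BY_DEH++ glucose library were thus not shared by the other glucose library, and for VEL1 mannitol is not singled out. PHO12, YPL257W-B and CUP1-1 have near copies with the same first 50 bases, so which copy the reads came from is uncertain. The YPL257W-B cluster is assigned to THI21 in the deposited table.

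The 3 measured genes for mannitol use were not higher in mannitol than in glucose. All 3 were higher in mannitol than in DEH in BY_DEH++, 2 of them by 2-fold or more. Of these 2, MAN2 stood at 1.05 CPM against a listed 0, so its fold depends on the pseudocount. The list median for DEH over mannitol was -1.04, or -0.31 with a pseudocount of 10 CPM. HXT17, a transporter of sugar alcohols, stood at 13.2 CPM in mannitol, 93.9 CPM in glucose and 8.65 CPM in DEH in BY_DEH++, and at 72.1 CPM in glucose and 5.42 CPM in DEH in BY_DEH+. DSF1, a mannitol dehydrogenase, stood at 95.2, 111 and 26.7 CPM in BY_DEH++ and at 190.4 and 35.4 CPM in BY_DEH+, and MAN2, its close relative, at 1.05, 7.01 and 0 CPM in BY_DEH++ and at 11.2 and 3.74 CPM in BY_DEH+, from a cluster that the deposited table assigns to HXT17. HXT13, HXT15, HXT16, SOR1 and SOR2 had no cluster near their starts, and XYL2 stayed below 10 CPM. These genes belong to families of close copies, and reads shared among copies may be missing from their values.

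**Figure D2:**
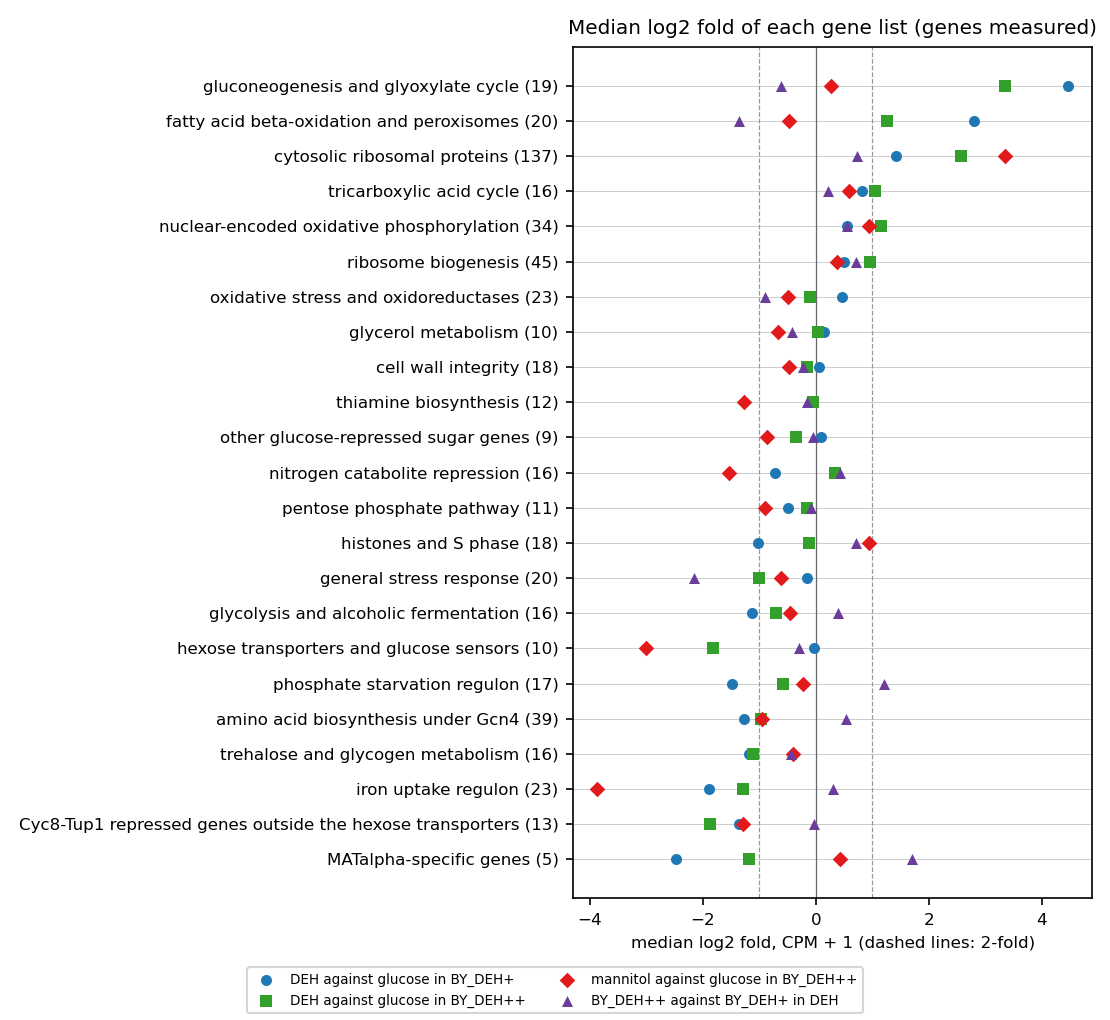
Median log2 fold (horizontal axis, CPM + 1) of each list with at least 5 measured genes, for DEH over glucose in each strain, mannitol over glucose, and BY_DEH++ over BY_DEH+ in DEH; numbers in parentheses are genes measured and dashed lines mark 2-fold. Ribosomal protein genes lie right of 0 in all 4 comparisons (1.43, 2.57, 3.35 and 0.73), and iron uptake genes lie left of 0 in the 3 media comparisons (-1.90, -1.28 and -3.88); with median-of-ratios scaling the sign turned for other glucose-repressed sugar genes and the cell wall in BY_DEH+ (to -0.03 and -0.06), thiamine in BY_DEH++ (to 0.03), phosphate in mannitol (to 0.20), and other glucose-repressed sugar, pentose phosphate and thiamine genes between the strains (to 0.15, 0.13 and 0.04).

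DEH was set directly against mannitol in BY_DEH++. Genes for gluconeogenesis and the glyoxylate cycle were higher in DEH, all 19 of them by 2-fold or more (median 2.94), and so were 15 of 20 genes of fatty acid oxidation (1.45) and 16 of 23 iron uptake genes (2.22). SFC1 stood at 501 CPM in DEH and 3.82 CPM in mannitol, DPA10 at 867 and 10.4 CPM, ZPS1 at 844 and 5.16 CPM, and HPF1, a cell wall mannoprotein, at 1814 and 16.8 CPM. Higher in mannitol were ANB1, COX5B and TIR1, at 56.7, 105 and 21.1 CPM against 0, 3.57 and 0 CPM in DEH, with 6.70, 67.7 and 45.4 CPM in glucose. Ribosomal protein genes were higher in mannitol too, 63 of 137 by 2-fold or more (median -0.80 for DEH over mannitol).

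Of all genes 254 were 4-fold or more higher in DEH and 136 lower (65.1% higher); median-of-ratios scaling gave 194 higher and 207 lower (48.4% higher) and upper-quartile scaling 195 and 198. With a pseudocount of 10 CPM 141 were higher and 83 lower. The remaining named genes were PHO12 and YHR214W, at 1027 and 342 CPM in DEH and listed at 0 in mannitol but with near copies elsewhere, and MTC7, MF(ALPHA)2 and RPS28A, at 31.2, 66.7 and 1558 CPM in mannitol against 0, 2.26 and 75.7 CPM. In the deposited table the YHR214W cluster is assigned to FLO5. The MTC7 cluster, 140 bp upstream of its start, is assigned there to HYP2 and MCM3 as well. Genes under nitrogen catabolite repression (10 of 16, median 1.21) and thiamine genes (7 of 12, median 1.53, or 0.61 with a pseudocount of 10 CPM) were higher in DEH, and histone and S phase genes lower (7 of 18, median -0.69). Medians near 0 changed sign with median-of-ratios scaling for oxidative phosphorylation (0.18 to -0.17), genes under Gcn4 (0.08 to -0.26) and the cell wall (0.21 to -0.13).

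Whether DEH and mannitol share a response was counted from comparisons with no library in common, DEH over glucose in BY_DEH+ and mannitol over glucose in BY_DEH++. They shared 28 higher genes, where independent lists would share 6.56, and 85 lower genes, where independent lists would share 16.7. Of the 28, 10 were not ribosomal protein genes. Both comparisons have a glucose culture as reference, and the glucose libraries of the strains differed little (11 genes higher and 17 lower at 4-fold). What is particular to the glucose cultures can thus enter both lists, so this overlap does not single out a shared response to DEH and mannitol. Within BY_DEH++, where both comparisons use the same glucose library, 105 higher and 77 lower genes were shared, 14 of the 105 outside the ribosomal proteins; part of this overlap may come from the shared library.

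The strains were compared in the same medium to ask how BY_DEH++ differs from BY_DEH+. In DEH, BY_DEH++ held less RNA from general stress and fatty acid oxidation genes and more from phosphate and histone genes. GRE1, a stress-induced hydrophilin (chromosome XVI, 128632 to 129138), stood at 30.7 CPM in BY_DEH++ against 2812 CPM in BY_DEH+, a ratio of 0.0109 (95% counting interval 0.0101 to 0.0118), and SSA3, a stress-induced Hsp70 chaperone, at 5.98 against 359 CPM. DSE1 and DSE2 stood at 1070 (1069.6) and 806 CPM against 59.7 and 34.8 CPM. Of the 20 general stress genes, 16 were at least 2-fold lower and none higher (median -2.16, percentile 0), with HSP12 at 392 against 5172 CPM.

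In DEH 75 genes were 4-fold or more higher in BY_DEH++ and 107 lower (41.2% higher), and median-of-ratios scaling gave 92 and 81 (53.2% higher). With a pseudocount of 10 CPM 40 were higher and 53 lower. The cultures were sampled at different days and densities, so strain and culture stage cannot be told apart in this medium.

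Of the fatty acid oxidation genes 13 of 20 were lower in BY_DEH++ in DEH (median -1.36), with POT1, the 3-ketoacyl-CoA thiolase, at 55.4 against 637 CPM, and of the oxidoreductases 11 of 23 were lower (-0.90). SHH3, SPG1, PIR3, YDL218W and LPX2 were among the 8 lowest, at 188, 408, 1516, 40.4 and 35.1 CPM in BY_DEH+ against 1.26, 4.68, 31.8, 0 and 0 CPM. The YDL218W and LPX2 clusters are assigned to DTD1 and SFK1 in the deposited table. Phosphate genes were higher in 11 of 17 (median 1.22), histone and S phase genes in 7 of 18 (0.72), ribosomal protein genes in 28 of 137 (0.73), ribosome biogenesis genes in 10 of 45 (0.72) and genes under Gcn4 in 12 of 39 (0.54). DUR3 and MEP2, transporters of urea and ammonium, stood at 96.6 and 149 CPM against 4.02 and 14.95 CPM (nitrogen list median 0.43), FIT2 at 3585 against 206 CPM (iron list median 0.31), and BUD4 and HOF1, of the bud neck, at 22.0 and 16.1 CPM in BY_DEH++ and listed at 0 in BY_DEH+. PHO12 and the CUP1 pair, which have near copies, were also named here. PHO12 stood at 1027 against 21.8 CPM, and its copy PHO11 was listed at 0 in both, so that the sum of the pair differed alike. CUP1-1 stood at 1377 against 9.06 CPM, and CUP1-2 was listed at 0 against 523 CPM, while their sum stood at 1377 against 532 CPM. Oxidative phosphorylation had a median of 0.55, gluconeogenesis -0.61, trehalose and glycogen -0.44 and the genes of alpha cells 1.70 (4 of 5 higher; 0.50 with a pseudocount of 10 CPM and 0.80 with clusters as the deposited table assigns them), with MF(ALPHA)1 at 1025 against 241 CPM.

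In glucose the strains differed little: 11 genes were 4-fold or more higher in BY_DEH++ and 17 lower, and 42 and 72 at 2-fold. VEL1 and YOR387C, close relatives of each other, stood at 305 and 39.6 CPM in BY_DEH++ against 3.08 and 0 CPM, and SSA3 at 3.09 against 57.3 CPM. The YOR387C cluster is assigned to PHR1 in the deposited table. The general stress list was lower here too (9 of 20, median -0.87, percentile 0), with HSP12 at 330 (330.5) against 1703 CPM, and no member was higher. Hexose transporters had a median of 0.55 (3 of 10 higher and 1 lower), the phosphate list 0.45 and ribosomal protein genes -0.36.

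The remaining named genes in glucose were CUP1-1 (2488 against 6.79 CPM), CUP1-2 (0 against 1320.4 CPM), YPL257W-B (267 against 1.49 CPM), ENA2 (35.2 against 0 CPM), COS1 (0 against 79.7 CPM), YER189W (0 against 14.8 CPM) and CPP3 (0 against 10.6 CPM); all but CPP3 have copies with the same first 50 bases. In the deposited table the YER189W cluster is assigned to PUG1 and YRF1-2, and the CPP3 cluster to ARO3 and LYS14. Without the genes that have such copies, 5 genes were 4-fold higher and 13 lower, with clusters as the deposited table assigns them 6 and 12, and with a pseudocount of 10 CPM 8 and 6.

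**Figure D3:**
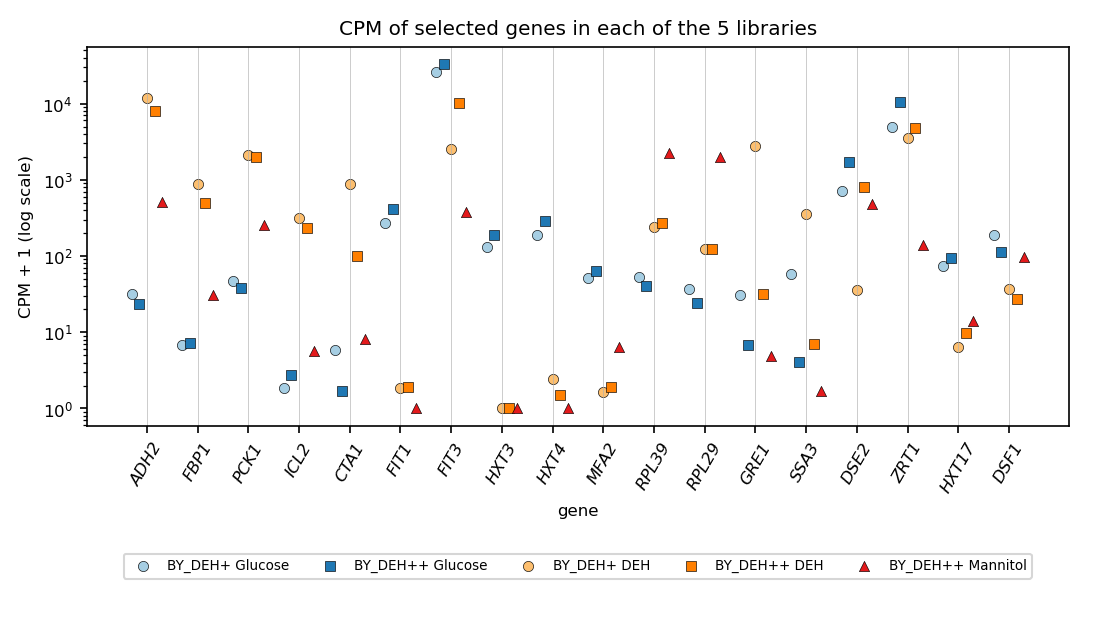
CPM + 1 on a log axis for 18 genes in each of the 5 libraries, 1 point per library. ADH2 and FBP1 lie highest in the DEH libraries, FIT1 and HXT4 in the glucose libraries, RPL29 and RPL39 in the mannitol library, and GRE1 in BY_DEH+ in DEH (2812 CPM).

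Start site use within genes was compared where a gene had at least 2 clusters. The share of a gene's CPM in its main cluster differed by 50 percentage points or more in 11 of 129 genes for DEH over glucose in BY_DEH+, 4 of 123 in BY_DEH++, 9 of 124 for mannitol over glucose, 10 of 122 for DEH against mannitol, 3 of 123 between the strains in DEH and 1 of 129 between them in glucose. GDH3, a glutamate dehydrogenase, used the cluster at its annotated start (chromosome I, 31102 to 31582) for 93.0% of its CPM in DEH and 4.02% in glucose in BY_DEH+, for 86.9% and 6.59% in BY_DEH++, and for 73.9% in mannitol. DCI1, of fatty acid oxidation, used the cluster at its start (chromosome XV, 675153 to 675229) for 91.7% in DEH and 6.71% in glucose in BY_DEH+, and for 83.5% and 8.97% in BY_DEH++. ATO3, a putative ammonium exporter (chromosome IV, 1241817 to 1242265), used the main cluster for 99.8% and 99.9% in DEH against 45.4% and 49.0% in glucose, with 2925 and 1752 CPM in DEH against 77.0 and 84.4 CPM. ADH4 was the gene that differed between the strains in glucose, with 27.1% of CPM in its upstream cluster in BY_DEH++ and 79.6% in BY_DEH+.

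Lists for other cell states and for strain markers were read beside these results. Of 20 meiosis and sporulation genes 4 passed the filter, each through its value in DEH in BY_DEH+, so their direction there was set by the filter and says nothing of the list. SPS100, of the spore wall, stood at 115 against 1.91 CPM there and IME2, the meiotic kinase, at 23.2 against 0 CPM. The median of the 4 was 1.18 in BY_DEH++ (-0.24 with clusters as the deposited table assigns them) and -0.49 in mannitol. The genes of alpha cells had a median of 0.43 for mannitol over glucose and those of a cells -3.67; in mannitol MFA1, MFA2, STE2 and AGA2 stood at 2.96, 5.45, 5.16 and 2.10 CPM, and MF(ALPHA)1, MF(ALPHA)2, STE3, SAG1 and AFB1 at 2367, 66.7, 90.2, 39.5 and 342 CPM. The marker genes HIS3, LEU2, MET17 and CAN1 were read in every library, HIS3 at 488 to 2866 CPM, LEU2 at 409 to 1071 CPM, MET17 at 1424 to 3234 CPM and CAN1 at 111 to 205 CPM, and URA3 and LYS2 had no cluster near their starts. The median of the 4 markers was -0.98 in DEH in BY_DEH+, -0.38 in DEH in BY_DEH++ and -0.73 in mannitol. TRP1 and ADE2 stayed below 10 CPM. No cluster lay on the mitochondrial chromosome.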

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

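The tests of gene span, noncoding RNA length, library batch and summed copies were chosen only after the result was seen. So was the use of the stress list to weigh culture stage and scaling. A screen for genes at least 2-fold higher in DEH than in glucose in 1 strain and at least 2-fold lower in the other picked 18 genes; each value is the log2 fold of DEH over glucose in BY_DEH++ less that in BY_DEH+. Values were higher in BY_DEH++ for PHO12 (5.04), DUR3 (4.84), DSE1 (3.56), MEP2 (3.13) and GDH1 (2.48). They were lower for YPL257W-B (-5.39), YCL042W (-4.20), YDL022C-A (-4.10), YDL218W (-4.04), SIP18 (-3.94), HXT6 (-3.84), YCL048W-A (-3.44), RNR3 (-3.19), THI4 (-3.02), PRR2 (-2.98), TRR2 (-2.76), PLN1 (-2.65) and EMP46 (-2.49). With 1 library per group these strain differences were not tested. PHO12, YPL257W-B and HXT6 have near copies. Summed with HXT7, the HXT6 folds came to -0.08 in BY_DEH+ and -1.79 in BY_DEH++, which are no longer opposite, while the sum of PHO11 and PHO12 gave -3.61 and 1.43, as PHO12 alone. The values of YCL042W, YDL022C-A and YDL218W rest on a library listed at 0, so that they depend on the pseudocount. A second screen asked for signal that no planned comparison used: clusters outside the gene windows that were 4-fold or more higher numbered 148 for DEH over glucose in BY_DEH+, 80 in BY_DEH++ and 210 for mannitol over glucose, against 313, 305 and 460 that were 4-fold or more lower.

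Ribosomal protein genes and short RNAs were high in the mannitol library. Ribosomal protein genes lay above other genes of like span and level by a median log2 of 3.77. Span includes introns, so a gene with introns was matched to genes with longer transcripts. That match thus cannot exclude better recovery of short transcripts as the whole cause. Their median for mannitol over glucose was 4.93 in the 8 genes up to 300 bp of span, 3.67 in 27 genes up to 600 bp and 3.26 in 99 genes up to 1200 bp. In the 3 longer ones it was 3.12. Other genes stood lower, at 0.89 in 165 genes up to 300 bp, -0.05 in 620 up to 600 bp and -0.64 in 1611 up to 1200 bp. The 2743 longer ones stood at -0.55. Even the 165 shortest other genes thus had a lower median than the ribosomal protein genes of every span. For DEH over glucose those 165 genes had medians of 0.01 in BY_DEH+ and -0.22 in BY_DEH++. A part played by length in the mannitol library stays open for both kinds of gene. For noncoding RNAs length and medium cannot be told apart, with a Spearman's rho of -0.36 between length and fold over 33 genes. Split at 500 bp, 22 of 26 shorter ones were 2-fold higher in mannitol (median 2.70) and 1 of 7 longer ones (median -0.51), so a part played by length stays open. A separate library batch cannot be told apart from mannitol itself, as mannitol has 1 library (ribosomal protein median -0.80 for DEH over mannitol).

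CUP1-1 and CUP1-2, which share their first bases, trade places between the strains. Reads shared between copies would leave the summed value far closer in the strains than either copy. The summed log2 fold was 0.91 in glucose and 1.37 in DEH, against 8.32 and 7.10 for CUP1-1. A true swap of copies between the strains would bring the sums closer as well, so the sum cannot tell these causes apart. The swap was fixed by strain. CUP1-2 was listed at 0 in glucose, DEH and mannitol in BY_DEH++, and CUP1-1 stood at 6.79 CPM in glucose and 9.06 CPM in DEH in BY_DEH+. A smaller difference of the sum is left over and was not explained.

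General stress genes were lower in BY_DEH++ than in BY_DEH+ in DEH. Scaling is excluded as the whole cause, since the DEH median was -2.16 as reported and -1.95 with median-of-ratios scaling. Culture stage in DEH and strain cannot be told apart: the list was lower in glucose too (median -0.87, percentile 0), but by less, and from 1 library of each strain.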

How the results depend on the processing

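The settings on ribosomal protein genes, recurring first bases and gene span were chosen only after the result was seen. Of the counts under other settings 153 stayed and 41 moved, and of the list medians 459 stayed, 26 moved and 1 of those at 2-fold or more changed sign, while medians nearer 0 whose sign turned with scaling are given beside their values in the results; the cause was not tested. Of the folds of named genes 25 stayed within their counting interval and 187 moved past it, with 0 changes of sign; of 106 named values past 4-fold, 106 were past it with median-of-ratios scaling and 98 with a pseudocount of 10 CPM. Values are given as higher and lower genes. A 2-fold limit gave 609 and 558 for DEH in BY_DEH+, 481 and 625 in BY_DEH++, 294 and 308 in both, 520 and 1537 for mannitol over glucose, 1188 and 487 for DEH over mannitol, 316 and 521 for the strains in DEH and 42 and 72 in glucose. A pseudocount of 10 CPM gave 138 lower for DEH in BY_DEH+, 69 lower in BY_DEH++, 54 and 42 in both, 182 lower for mannitol over glucose, 141 and 83 for DEH over mannitol, 40 and 53 for the strains in DEH and 6 lower in glucose. Median-of-ratios scaling gave 232 lower for mannitol over glucose and 207 lower for DEH over mannitol, and upper-quartile scaling 250 lower for mannitol over glucose. A filter at 50 CPM gave 7 higher for the strains in glucose. Clusters as assigned in the deposited table gave 6 higher there and 54 higher for DEH in both strains, and turned the meiosis list in BY_DEH++ from 1.18 to -0.24. The limma fit, which pairs DEH and glucose by strain, gave 261 and 264 for DEH at an adjusted p below 0.05, from 1 residual degree of freedom. Its only residual is how far the DEH response differs between the strains, so the strains stand in for replicates. Counting both media against the shared glucose library gave 105 higher genes in common. A 30-point limit for start sites gave 7 for DEH in BY_DEH++, 17 for mannitol over glucose and 5 for the strains in DEH. Of settings added after the data were seen, leaving out ribosomal protein genes gave 84 higher for DEH in BY_DEH++, 97 for mannitol over glucose and 10 in the overlap. Leaving out recurring first bases gave 5 higher for the strains in glucose, and subtracting the median of genes of like span gave 223 lower for mannitol over glucose. The same subtraction turned mannitol list medians from -0.46 to 0.18 for glycolysis and from -0.40 to 0.18 for trehalose and glycogen. It turned them from -0.47 to 0.15 for fatty acid oxidation and from -0.47 to 0.08 for the cell wall. Depth limits the low end: 10 CPM rested on 94 to 199 reads and the lowest listed values rested on 5 to 10 reads.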

Other observations

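The tests on signal outside genes, on zinc genes without FET4 and on copper genes were chosen only after the result was seen, while the zinc prediction was written before its test. Outside the gene windows 1477 clusters reached 10 CPM, of which 634 lay between genes, 448 inside coding genes in sense, 306 in antisense and 89 at noncoding RNA genes. SNR17B, a U3 small nucleolar RNA (chromosome XVI, 281056 to 281517), stood at 14651 CPM in mannitol against 32.5 CPM in glucose and 11.0 CPM in DEH in BY_DEH++. SNR34 stood at 2476 against 222 CPM. SCR1, the RNA of the signal recognition particle, was higher in DEH in both strains, at 1081 and 731 CPM against 226 and 153 CPM. Of the 306 antisense clusters 79 were 4-fold lower in DEH in BY_DEH+ and 94 in BY_DEH++, against 32 and 8 higher. Of all 1477 clusters 313 and 305 were lower, against 148 and 80 higher, so an excess of lower clusters was not particular to antisense. A cluster inside UGA2 (chromosome II, 247783 to 248189) stood at 0.56 CPM in DEH and 165 CPM in glucose in BY_DEH+.

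Genes of iron uptake were low in mannitol, and so were ZRT1 and ZPS1, which the zinc regulator Zap1 controls. If the mannitol medium held more available metal, further Zap1 targets would be lower as well. The median of 10 such genes was -1.75 for mannitol over glucose, in line with that idea, with 7 of 10 lower by 2-fold, and -1.35 with median-of-ratios scaling. That comparison rests on 1 glucose library that itself stood apart. The list was higher in it than in BY_DEH+ in glucose (median 0.62, percentile 100), and lower in DEH than in it (median -1.02). By that comparison alone the medium is not singled out. DEH over mannitol in BY_DEH++, which leaves that library out, had a list median of 1.38 (percentile 99.93), or 1.04 with median-of-ratios scaling. Of the 10 genes, 6 were 2-fold lower in mannitol there and 1 was higher. The mannitol side still rests on 1 library. FET4, also on the iron list, carries part of the fall from glucose to mannitol. Without it the median of 9 genes for mannitol over glucose was -1.32, and -0.92 with median-of-ratios scaling, short of the -1 set beforehand. For DEH over mannitol the 9 genes had a median of 1.62, or 1.28 with that scaling. Against the idea, CUP1, induced by copper, was lower in mannitol (25.3 against 2488 CPM for the summed copies). CTR1, a copper transporter outside the iron list, was lower (log2 fold of -2.22), as more copper would leave it. A test would measure iron, zinc and copper in each medium and repeat the mannitol culture with metals matched.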
